A study of Mus musculus with 15 samples.

How the data were processed

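Total RNA of 15 mouse livers was extracted with TRIzol and made into RNA sequencing libraries with the VAHTS Universal V6 kit, whose strand setting the labels do not state. The values are the authors' FPKM as deposited, with 1 column per library and no pooling, not rescaled for the main test. The submitters' processing notes name fastp, HISAT2, HTSeq and DESeq2 and the build mm10, without versions, roles or order, and state neither the gene annotation nor a filter. A series table and 15 single files held equal values (largest difference 0 FPKM). Of 17527 genes, 17051 were above 0 in at least 1 library, and 16906 symbols matched 1 gene of GENCODE M21, from which positions on GRCm38 were taken.

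Libraries were grouped by their labels: control 1_1, 1_5, 2_1, 2_2 and 3_4; model 1_1, 1_4, 2_1, 2_3 and 3_4; and BBBPH 2_1, 2_2, 3_1, 3_2 and 3_4. The meaning of the replicate numbers is not stated, so they formed no block in the main test. As a check, residuals of the 8 pairs of libraries with the same number in different groups correlated between -0.33 and 0.02, and 0 of 10 such libraries correlated best with their own number. No library was left out of the main test. Depth was read from the values, since FPKM made from whole counts stand in whole-number ratios within a gene once each library is multiplied by 1 constant. It came to 36.29 ± 0.64 (control), 36.95 ± 0.77 (model) and 37.86 ± 1.2 (BBBPH) in 1e+06 fragments, and lengths were recovered for 15299 genes with 100% of values above 0 within 0.02 of a whole number. In simulated data of 4000 genes, 99.64% of recovered counts equalled the simulated ones. Chi-square per gene between the 30 pairs of libraries within a group was 37.9 to 477, where sampling noise alone gives 1, so that no library was a copy of another.

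Genes with a mean of at least 1 FPKM (9575) were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(FPKM + 1). The fit had 3 group means over the 15 libraries (12 residual degrees of freedom) and eBayes with trend=TRUE. The 2-sided p-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Lists of genes (27) and of cell type markers (14) were written from general knowledge of mouse liver. The 36 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list. Lists of T and NK cells, B and plasma cells, dendritic cells, cholangiocytes and adipocytes had fewer than 5 tested members and were compared by score alone. Scores of the 14 marker lists were means of standardized log2 values and were compared by exact 2-sided permutation tests over 252 arrangements, with a smallest p of 0.00794, adjusted over the 14 scores. That p is also the probability by chance that the libraries of both groups do not overlap. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading and plotting. The limma procedure was tested on simulated data with changes added to a set of genes over normal noise of each gene's residual size. At a log2 fold change of 1 it recovered 97%, 97% and 92.5% of them in the 3 comparisons, and 2%, 3.5% and 4.5% of calls were unchanged genes. At 0.5 it recovered 73.1%, 68.7% and 77.6%.

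Genes were named by a rule. It took, per comparison, the 6 largest rises and 6 largest falls (3 and 3 for BBBPH against control) among called genes with at least 5 FPKM in the higher group and no overlap between groups, skipping clone, Gm and Rik symbols. It added the members with the smallest adjusted p from each list that was called or had at least 3 called members, and 20 genes whatever their values, from Cyp7a1 to Sqle. For the opposite changes it took the 6 genes with the smallest larger adjusted p. The rule allowed 2 to 4 members per list. The number was settled at 2 after a first run with 4 had been seen, which had named 247 genes, with 66 outlying values in single libraries, in place of 149 genes with 37. These counts leave out 6 of the 155 genes that the rule took, which are not reported here and were not replaced, and which stay in the tests and lists. Groups, lists, tests, this rule and the alternatives were chosen before the data were examined, except where stated.

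Alternatives chosen then were a pseudocount of 0.1, no filter, a filter at 5 FPKM, TPM, median-ratio scaling (size factors from median ratios over genes), quantile scaling, eBayes with trend=FALSE or robust=TRUE, library weights, a fit of 2 groups, a fold minimum of 1 on the log2 scale, the replicate number or its first digit as a block, and each library left out in turn. Alternatives chosen after seeing the data were voom on recovered counts (9570 genes), the 20 most abundant genes left out, the 2 or 3 libraries that stood apart left out, a clock score as covariate, a list of 18 heat-shock genes, tested also without 3 of them, and clock scores without genes seen before. Opposite changes were compared with 100 simulations of unchanged groups that share the model libraries and with 20 splits of the model libraries. Mitochondrially encoded genes are not among the genes of the files.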

Results

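RNA was sequenced from the livers of 15 mice in 3 groups of 5. Control mice were compared with mice that had a diet-induced nonalcoholic steatohepatitis (model), and with mice on the same diet that also received biotransformed bear bile powder (BBBPH). The diet of both latter groups gave 60% of its energy as fat, 20% as protein and 20% as carbohydrate, with 0.2% cholesterol. Their water held 42 g/L of sugar, 55% of it sucrose and 45% fructose. The diet lasted 20 weeks. After week 12, BBBPH mice were dosed by mouth each day with 150 mg/kg of the powder and model mice with saline. The labels give 14 mice in the dosed group, of which 5 were sequenced, and do not say what the control mice ate. Each library held FPKM values for 17527 genes, resting on 35395712 to 39624160 fragments. A single fragment in a gene of 1 kilobase gave 0.0252 to 0.0283 FPKM. Values are means ± SD (n = 5 libraries), and fold changes are on the scale of log2(FPKM + 1), which makes them smaller for genes near 1 FPKM.

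In a principal component analysis of the 9575 genes with a mean of at least 1 FPKM, the groups formed separate sets of points. Model libraries lay at 16.59 to 29.6 on component 1, which held 31.9% of the variance, and all control and BBBPH libraries lay below 0. Control libraries lay at 10.7 to 19.6 on component 2, which held 22.3%, and all BBBPH libraries lay below 0. A single library in each group stood apart in genes of a particular kind. BBBPH 2_2 held 978 FPKM of Ctrb1, which encodes the pancreatic enzyme precursor chymotrypsinogen B, against at most 0.906 in the other 14 libraries. Model 1_4 held 14965 FPKM of the acute-phase gene Saa2, against 61.6 to 194 in the other model libraries. Control 2_1 held 70 FPKM of Tnnt3, a troponin of fast skeletal muscle, against at most 0.145 in the other control libraries.

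**Figure D1:**
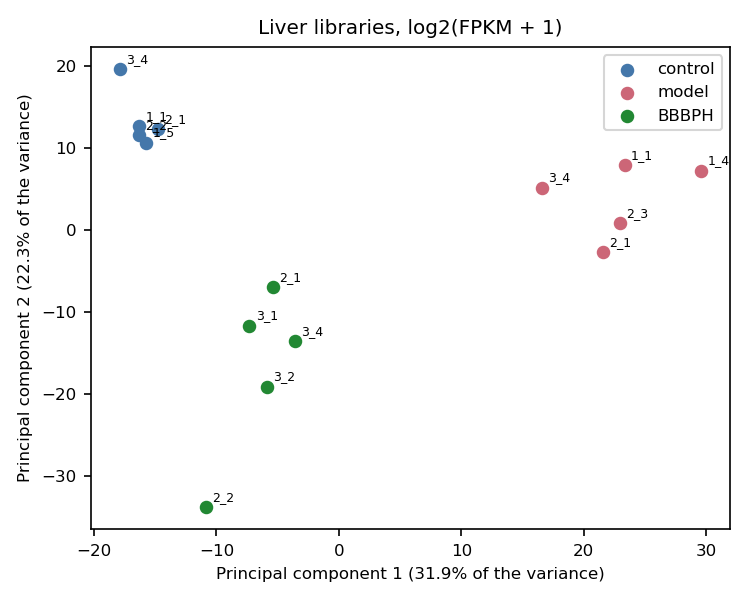
Scores of the 15 liver libraries on principal components 1 and 2 of log2(FPKM + 1), in arbitrary units, each point a library with its replicate number. Model libraries lie at 16.59 or more on component 1, and BBBPH 2_2 lies lowest on component 2 at -33.84.

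**Figure D2:**
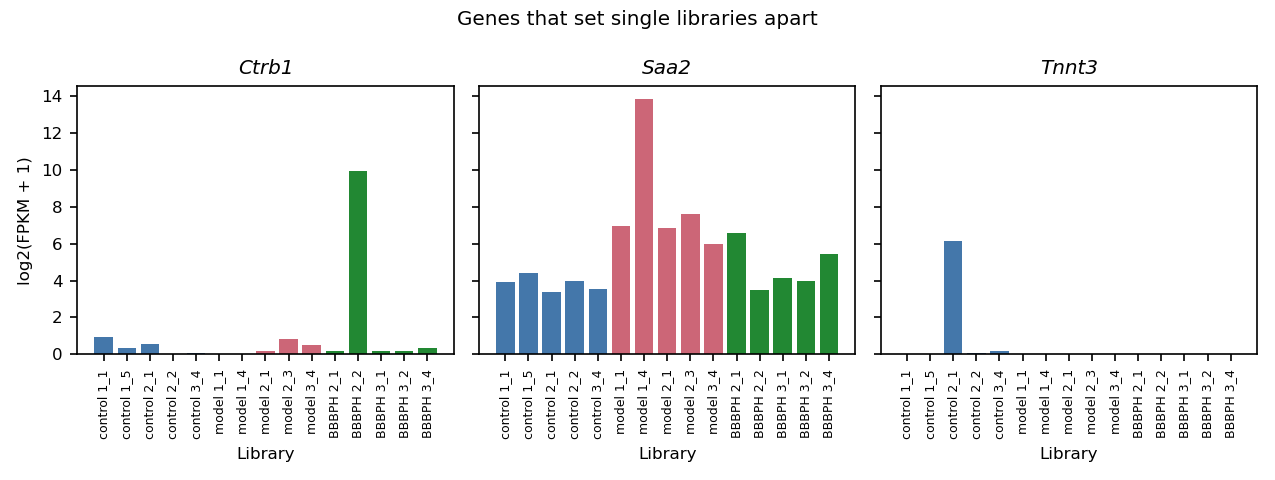
Bars give log2(FPKM + 1) of Ctrb1, Saa2 and Tnnt3 in each of the 15 libraries, coloured by group. Ctrb1 is high in BBBPH 2_2 (978 FPKM), Saa2 is highest in model 1_4 (14965 FPKM), and Tnnt3 is high in control 2_1 (70 FPKM).

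The comparison of model with control libraries asked what the diet model changed in the liver. The fatty acid transporter gene Cd36 rose from 10 ± 1.90 to 80.4 ± 17.0 FPKM (log2 fold change 2.87, adjusted p = 5.16e-08), and the lipid droplet coat gene Plin4 rose from 0.878 ± 0.157 to 13.0 ± 3.79 FPKM (log2 fold change 2.85, adjusted p = 5.16e-08). Scd1, the stearoyl-CoA desaturase, fell from 2442 ± 689 to 817 ± 358 FPKM (log2 fold change -1.67, adjusted p = 0.00492). Hspa5, which encodes the endoplasmic reticulum chaperone BiP, rose from 282 ± 45.8 to 842 ± 171 FPKM (log2 fold change 1.56, adjusted p = 8.72e-06). Among genes with a sex bias in mouse liver, male-biased Hsd3b5 fell from 157 ± 17.2 to 13.7 ± 19.2 FPKM (log2 fold change -4.24, adjusted p = 5.44e-05) and female-biased Cyp2b9 rose from 0.0899 ± 0.0624 to 79.9 ± 51.9 FPKM (log2 fold change 5.96, adjusted p = 2.80e-06). In the GRCm38 assembly Cd36 lies at chromosome 5, 17781690 to 17888801, Plin4 at chromosome 17, 56100591 to 56109803, Scd1 at chromosome 19, 44394455 to 44407879 and Hspa5 at chromosome 2, 34771970 to 34777547. Hsd3b5 lies at chromosome 3, 98618634 to 98630252 and Cyp2b9 at chromosome 7, 26173411 to 26210661.

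By limma, 3692 of 9575 genes tested changed, 2865 higher and 827 lower in the model. The count was 3364 without model 1_4 and BBBPH 2_2, and 3211 without control 2_1 as well, both run after the values had been seen. The median log2 fold change of all genes tested was 0.117 here, 0.019 in BBBPH against model and 0.133 in BBBPH against control. Gene lists are therefore described by a relative median, the median log2 fold change of the list minus that of all genes tested, and a list that rose or fell did so against all other genes. As TPM, 3007 genes were higher and 785 lower. With median-ratio scaling 1483 were higher and 1809 lower, and with quantile scaling 1499 and 1742. These scalings centre the genes by construction, so the loss of the excess of higher genes under them cannot decide whether it was real. Alternatives under which a call was gained or lost are named beside it, apart from the replicate blocks and the fold minimum. Those with 2 libraries out leave out model 1_4 and BBBPH 2_2, and those with 3 also control 2_1. The rule for named genes gave as largest rises Cyp2b9, Lcn2, Saa2 and Saa1 of the acute phase, complement factor D (Cfd) and the metallothionein Mt2, with log2 fold changes of 4.51 for Lcn2, 4.40 for Saa2, 3.54 for Saa1, 3.51 for Cfd and 3.21 for Mt2. Without model 1_4 alone these 5 were 3.34, 3.0, 2.34, 3.33 and 2.42. It gave as largest falls Hsd3b5, the anion transporter Slco1a1, Cyp4a12b, Cib3, Igfbp2 and Cnmd, with -2.60 for Slco1a1, -2.58 for Cyp4a12b, -2.25 for Cib3, -2.16 for Igfbp2 and -2.15 for Cnmd.

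Of lipid droplet and lipid uptake genes, 13 of 20 rose and 1 fell (15 changed adjusted over the list alone). The list rose (relative median 0.64, adjusted p = 0.00464), with adjusted p = 0.362 with an estimated correlation. Plin2, the main droplet coat protein of hepatocytes, rose from 159.9 ± 51.7 to 274 ± 17.6 FPKM (log2 fold change 0.82, adjusted p = 0.0125). Of de novo lipogenesis genes, 1 of 19 rose and 10 fell (11 changed adjusted over the list alone). The list fell (relative median -0.76, adjusted p = 2.35e-06), with adjusted p = 0.273 with an estimated correlation. Log2 fold changes were -1.24 for Fads2, -2.06 for Elovl6, -0.88 for Fasn and -0.82 for Srebf1, among them a desaturase, an elongase, the fatty acid synthase and the regulator SREBP1. The call of Fasn ended without control 1_1 or 2_1 or with 2 libraries out or 3 libraries out (adjusted p = 0.0555 to 0.111). Of apolipoprotein and lipoprotein genes, 1 of 20 rose and 4 fell (5 changed adjusted over the list alone). They fell as a list (relative median -0.15, adjusted p = 0.0206), with adjusted p = 0.273 with an estimated correlation, and the first call ended without model 1_4 or with 2 libraries out (adjusted p = 0.0587 and 0.0525). Apom, a component of high density lipoprotein, had a log2 fold change of -0.84, and Apoa4 1.31. Of fatty acid oxidation and PPAR-alpha target genes, 9 of 30 rose and 0 fell (9 changed adjusted over the list alone), with log2 fold changes of 1.95 for Vnn1 and 0.60 for Etfdh. The list did not pass (relative median 0.05, adjusted p = 0.551). Of cholesterol synthesis genes, 3 of 24 rose and 5 fell (8 changed adjusted over the list alone). They did not pass as a list (relative median -0.10, adjusted p = 0.125) except without control 3_4 or model 3_4 or with 3 libraries out (adjusted p = 0.0236 to 0.0333). Hmgcs1 rose from 14.5 ± 3.51 to 38.9 ± 8.43 FPKM (log2 fold change 1.36, adjusted p = 2.83e-05). The squalene epoxidase gene Sqle, with 2.43 ± 1.85 and 4.58 ± 2.64 FPKM, was not called (log2 fold change 0.71, adjusted p = 0.117) except without control 1_5 or model 2_3 (adjusted p = 0.0311 and 0.0486).

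Of bile acid synthesis genes, 6 of 17 rose and 5 fell (12 changed adjusted over the list alone), and the list did not pass (relative median -0.07, adjusted p = 0.375). Rises were called for Hsd3b7 (log2 fold change 1.30 ± 0.13 SE, adjusted p = 7.22e-06) and the side-chain oxidase Acox2 (log2 fold change 0.90 ± 0.12 SE, adjusted p = 8.71e-05). Cyp7a1, the rate-limiting enzyme of the classic pathway, had 33.9 ± 17.4 FPKM in control and 29.9 ± 15.2 in model libraries (log2 fold change -0.15, adjusted p = 0.88). Cyp8b1, the 12-alpha-hydroxylase of cholic acid synthesis at chromosome 9, 121914356 to 121916305, rose from 92.5 ± 20.8 to 194 ± 76.0 FPKM (log2 fold change 1.0, adjusted p = 0.0354). This call ended without control 1_1, 2_1, 2_2, 3_4, model 1_1, 2_1 or 3_4 or with no filter, median-ratio scaling, quantile scaling, a robust fit or 20 top genes out (adjusted p = 0.0517 to 0.0916). Nr0b2, which encodes the receptor SHP, rose from 6.05 ± 1.41 to 14.5 ± 7.12 FPKM (log2 fold change 0.98, adjusted p = 0.0374). This call ended without control 1_1, 1_5, 2_2, 3_4, model 1_1, 2_1, 2_3 or 3_4 or with no filter, median-ratio scaling, quantile scaling, a robust fit, a 2-group fit, voom or 20 top genes out (adjusted p = 0.0504 to 0.0986). Nr1h4, which encodes the bile acid receptor FXR, had 49.2 ± 4.83 and 53.1 ± 7.74 FPKM (log2 fold change 0.10, adjusted p = 0.487). Of bile acid and sterol transporters, 2 of 12 rose and 5 fell (8 changed adjusted over the list alone), and the list did not pass (relative median -0.18, adjusted p = 0.114). The named members had log2 fold changes of 1.44 for Abcc3, -0.94 for Abcg5 and 0.47 for Abcb11, the bile salt export pump, whose call ended with median-ratio scaling (adjusted p = 0.0714). Of FXR-induced genes, 2 of 10 rose and 1 fell (3 changed adjusted over the list alone), among them Cyp4f15 (log2 fold change -0.41 ± 0.07 SE, adjusted p = 0.000596). Together they did not pass (relative median -0.15, adjusted p = 0.313), with mean and median of different sign. Of target genes of the xenobiotic receptors PXR and CAR, 4 of 21 rose and 2 fell (6 changed adjusted over the list alone), among them Aldh1a1 (log2 fold change 1.47 ± 0.14 SE, adjusted p = 6.53e-06). The list did not pass (relative median -0.17, adjusted p = 0.237), again with signs that differed. Cyp3a11 had 916 ± 223 and 591 ± 283 FPKM and was not called (log2 fold change -0.75, adjusted p = 0.0536) except without control 1_5, model 1_1 or 2_1 or with median-ratio scaling, library weights or a clock covariate (adjusted p = 0.0119 to 0.0479). Without model 1_4 its change was -0.44. Nr1i2, which encodes PXR, fell from 30.3 ± 3.54 to 24.6 ± 1.20 FPKM (log2 fold change -0.29, adjusted p = 0.0153).

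Of extracellular matrix and fibrosis genes, 12 of 18 rose and 0 fell (14 changed adjusted over the list alone). They rose as a list (relative median 0.33, adjusted p = 8.84e-05), with adjusted p = 0.332 with an estimated correlation. Col1a1, a chain of type I collagen, rose from 0.701 ± 0.310 to 2.56 ± 0.912 FPKM (log2 fold change 1.04, adjusted p = 0.000427), with log2 fold changes of 1.21 for Col4a1 and 2.10 for Mmp12 for a basement membrane collagen and a macrophage elastase. Stellate cell and fibroblast markers moved beside them: 11 of 14 rose and 0 fell (12 changed adjusted over the list alone), and the list rose (relative median 0.29, adjusted p = 0.00655), with adjusted p = 0.332 with an estimated correlation. Log2 fold changes were 0.75 for Col14a1 and 0.53 for Cygb. Of cytokine, chemokine and innate sensor genes, 13 of 22 rose and 0 fell (13 changed adjusted over the list alone). They did not pass as a list (relative median 0.36, adjusted p = 0.0703) except without model 1_1, 2_1 or 2_3 or with no filter, median-ratio scaling or 20 top genes out (adjusted p = 0.000114 to 0.0499). Ccl2, a chemokine that draws monocytes, rose from 0.649 ± 0.316 to 5.02 ± 2.46 FPKM (log2 fold change 1.78, adjusted p = 9.81e-05), and log2 fold changes were 1.84 for Il1rn and 1.63 for Cxcl10. Tnf had a mean below 1 FPKM and was not tested, with 0.0465 ± 0.0637 FPKM in control, 0.431 ± 0.240 in model and 0.0605 ± 0.0369 in BBBPH libraries. Of acute-phase genes, 11 of 20 rose and 0 fell (12 changed adjusted over the list alone), with log2 fold changes of 0.94 for Lbp and 1.78 for Orm3. Together they rose (relative median 0.85, adjusted p = 0.0367), with adjusted p = 0.736 with an estimated correlation, and the first call ended without control 1_5, 2_1 or 2_2 or with voom (adjusted p = 0.0507 to 0.0667). Its relative median was 0.52 without model 1_4. Of interferon-stimulated genes, 15 of 20 rose and 1 fell (17 changed adjusted over the list alone), with log2 fold changes of 1.03 for Rsad2 and 0.92 for Cmpk2. The members rose as a list (relative median 0.58, adjusted p = 0.0025), with adjusted p = 0.675 with an estimated correlation. Of MHC class II genes, 1 of 6 rose and 0 fell (0 changed adjusted over the list alone), and the list did not pass (relative median 0.30, adjusted p = 0.375). Without control 2_1 its relative median was 0.18.

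Of unfolded protein response genes, 18 of 22 rose and 0 fell (18 changed adjusted over the list alone). The set as a whole rose (relative median 0.96, adjusted p = 4.36e-08), with adjusted p = 0.313 with an estimated correlation. Sel1l and Syvn1, partners in the degradation of misfolded proteins, and the disulfide isomerase Pdia4 had log2 fold changes of 0.95 for Sel1l, 1.92 for Syvn1 and 1.75 for Pdia4. Of antioxidant and NRF2 target genes, 12 of 20 rose and 2 fell (15 changed adjusted over the list alone), with log2 fold changes of 1.48 for Srxn1, 0.87 for Sod3 and -1.53 for Gstp1. Together they did not pass (relative median 0.23, adjusted p = 0.0676) except without model 1_4 or with no filter, median-ratio scaling, 2 libraries out, 3 libraries out or 20 top genes out (adjusted p = 0.00857 to 0.0453). Of PI3K-AKT and insulin signalling genes, 2 of 23 rose and 9 fell (11 changed adjusted over the list alone). Together they fell (relative median -0.20, adjusted p = 0.00138), with adjusted p = 0.362 with an estimated correlation. Egfr, the epidermal growth factor receptor, fell (log2 fold change -1.18 ± 0.26 SE, adjusted p = 0.00233). Pik3cd rose (log2 fold change 0.35 ± 0.09 SE, adjusted p = 0.00596), a call that ended with quantile scaling (adjusted p = 0.0811). Of glucose metabolism genes, 6 of 23 rose and 4 fell (10 changed adjusted over the list alone), and the list did not pass (relative median -0.15, adjusted p = 0.156). The log2 fold change was -1.34 for Gys2, the liver glycogen synthase. Of genes of arginine synthesis, the urea cycle and nitric oxide, 7 of 19 rose and 6 fell (15 changed adjusted over the list alone), and the list did not pass (relative median -0.19, adjusted p = 0.111) except without control 3_4 (adjusted p = 0.0327). The named members had log2 fold changes of -1.02 for Cps1, -0.81 for Ass1 and 0.77 for Glul, a pair of urea cycle enzymes and the glutamine synthetase. Arg1 had 862 ± 133 and 699.8 ± 42.5 FPKM and was not called (log2 fold change -0.29, adjusted p = 0.0804) except without control 3_4 or with median-ratio scaling, library weights or 20 top genes out (adjusted p = 0.0102 to 0.04). Nos3, the endothelial nitric oxide synthase, rose from 0.902 ± 0.158 to 1.48 ± 0.225 FPKM (log2 fold change 0.38, adjusted p = 0.00503), a call that ended with quantile scaling (adjusted p = 0.0502).

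Of male-biased liver genes, 0 of 22 rose and 16 fell (17 changed adjusted over the list alone), and the list fell (relative median -1.06, adjusted p = 1.52e-09), with adjusted p = 0.273 with an estimated correlation. Of female-biased genes, 4 of 7 rose and 0 fell (5 changed adjusted over the list alone), among them Cyp2a22 (log2 fold change 2.84 ± 0.35 SE, adjusted p = 3.61e-05). The list did not pass (relative median 0.85, adjusted p = 0.326). Of circadian clock genes, 2 of 15 rose and 6 fell (9 changed adjusted over the list alone), with a log2 fold change of -0.75 for Per2. The members fell as a list (relative median -0.51, adjusted p = 0.0025), with adjusted p = 0.273 with an estimated correlation. Of periportal hepatocyte genes, 3 of 20 rose and 7 fell (11 changed adjusted over the list alone), among them the glutaminase Gls2 (log2 fold change -0.89 ± 0.15 SE, adjusted p = 0.000347). As a list they fell (relative median -0.40, adjusted p = 0.000405), with adjusted p = 0.273 with an estimated correlation. Of pericentral genes, 6 of 16 rose and 2 fell (10 changed adjusted over the list alone), with a log2 fold change of 1.07 for Rhbg. They did not pass as a list (relative median 0.14, adjusted p = 0.375). Of nuclear-encoded oxidative phosphorylation genes, 1 of 36 rose and 2 fell (0 changed adjusted over the list alone). The list fell (relative median -0.17, adjusted p = 0.00517), with adjusted p = 0.736 with an estimated correlation, and the first call ended without model 1_4 or with 2 libraries out or 3 libraries out (adjusted p = 0.0538 to 0.111). Cyc1 fell (log2 fold change -0.29 ± 0.09 SE, adjusted p = 0.0203), except without control 1_5 or model 3_4 or with 2 libraries out or 3 libraries out (adjusted p = 0.0509 to 0.075). Ndufb3 rose (log2 fold change 0.40 ± 0.12 SE, adjusted p = 0.0184), except without model 2_3 or with median-ratio scaling (adjusted p = 0.0525 and 0.114). Of proliferation genes, 4 of 9 rose and 1 fell (5 changed adjusted over the list alone), with log2 fold changes of -1.45 for Tk1 and 2.68 for Cdkn1a, the latter encoding the cell cycle inhibitor p21. Together they did not pass (relative median -0.03, adjusted p = 0.999). Of immediate early genes, 5 of 14 rose and 2 fell (7 changed adjusted over the list alone), with log2 fold changes of -2.19 for Myc and -0.39 for Klf2, and the list did not pass (relative median 0.04, adjusted p = 0.422). Both of these lists had signs that differed between median, mean and test.

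Of hepatocyte markers, 0 of 14 rose and 5 fell (5 changed adjusted over the list alone), with a log2 fold change of -0.40 for Serpina1a. They fell as a list (relative median -0.35, adjusted p = 0.0022), with adjusted p = 0.273 with an estimated correlation. Of monocyte-derived and lipid-associated macrophage markers, 7 of 12 rose and 1 fell (8 changed adjusted over the list alone), with a log2 fold change of 0.94 for Lgals3. The list did not pass (relative median 0.71, adjusted p = 0.0734) except without model 1_1 or 3_4 or with no filter, median-ratio scaling or 20 top genes out (adjusted p = 0.000666 to 0.0328). Without model 1_4 its relative median was 0.41. Markers of Kupffer cells (relative median 0.02, adjusted p = 0.494), neutrophils (relative median 0.72, adjusted p = 0.348) and endothelium (relative median -0.04, adjusted p = 0.895) did not pass as lists, except neutrophils with 3 libraries out (adjusted p = 0.0274). For Kupffer cells the median and the test differed in sign. Neither did those of pancreas and gut (relative median -0.15, adjusted p = 0.228) and of erythroid cells (relative median -0.42, adjusted p = 0.102), the latter except without control 3_4 or with no filter (adjusted p = 0.0266 and 0.0112) and with a relative median of -0.21 without control 2_2. Among single markers the rule named the endothelial genes Lyve1 and Pecam1 and the adipocyte genes Cfd and Car3, with log2 fold changes of 1.36 for Lyve1, 0.33 for Pecam1 and 1.40 for Car3. Skeletal muscle markers passed as lower (relative median -1.34, adjusted p = 0.0245), with adjusted p = 0.676 with an estimated correlation, and the first call ended without control 2_1 or with median-ratio scaling, 3 libraries out, voom or 20 top genes out (adjusted p = 0.0629 to 0.276). Without control 2_1 the relative median was -0.13. None of 6 members was called, with Mylpf (log2 fold change -1.35, adjusted p = 0.117) and Tnnt3 (log2 fold change -1.27, adjusted p = 0.263) named by the rule. Their changes were -0.46 and -0.05 without control 2_1. Marker scores, means of standardized values over all members of a list, were compared by exact permutation tests over 14 lists. They differed for hepatocytes (model minus control -0.60), monocyte-derived macrophages (1.33), dendritic cells (1.11) and stellate cells (1.46), each with exact p = 0.00794, the smallest possible, and adjusted p = 0.0278. Of the 10 dendritic cell markers 0 reached a mean of 1 FPKM, so that score rested on values near the floor. Leaving out any control library (1_1, 1_5, 2_1, 2_2 or 3_4), or 3 libraries, ended the 4 calls, with adjusted p of 0.0556 to 0.0833. Leaving out 1 model library gave 4 or 5 calls, so fewer libraries alone do not explain the losses without 1 control. The call of hepatocytes also ended with TPM (adjusted p = 0.0556) or quantile scaling (adjusted p = 0.208). The score of T and NK cells differed by 0.46 (adjusted p = 0.175) and passed without model 1_1 (adjusted p = 0.0444). Scores of B cells (0.23, adjusted p = 0.615), cholangiocytes (-0.16, adjusted p = 0.395) and adipocytes (0.44, adjusted p = 0.444) were not called. That of B cells was 0.03 without control 1_1, 0.15 without control 3_4 and 0.08 without model 2_1. Ribosomal protein genes took 4.98 ± 0.49% of the FPKM in control and 4.22 ± 0.25% in model libraries (exact permutation p = 0.0159). Among genes named as changed, the libraries of both groups overlapped for Fasn, Srebf1, Apoa4, Cyp8b1, Nr0b2, Cyc1, Ndufb3 and Myc, and for no others.

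The comparison of BBBPH with model libraries asked what dosing changed in mice kept on the same diet. Hspa5 fell from 842 ± 171 to 175 ± 36.7 FPKM (log2 fold change -2.26, adjusted p = 1.41e-06), and Manf, a secreted factor of the endoplasmic reticulum stress response, fell from 328 ± 59.6 to 66.2 ± 13.5 FPKM (log2 fold change -2.30, adjusted p = 1.41e-06). Cd36 fell from 80.4 ± 17.0 to 22.1 ± 3.29 FPKM (log2 fold change -1.80, adjusted p = 4.76e-06), and Col1a1 fell from 2.56 ± 0.912 to 0.889 ± 0.327 FPKM (log2 fold change -0.89, adjusted p = 0.00184). Sqle rose from 4.58 ± 2.64 to 16.1 ± 2.65 FPKM (log2 fold change 1.74, adjusted p = 0.00187) and the fatty acid desaturase gene Fads2 rose from 161 ± 31.6 to 545 ± 85.2 FPKM (log2 fold change 1.76, adjusted p = 2.93e-06), while Scd1 fell from 817 ± 358 to 115 ± 70.6 FPKM (log2 fold change -2.90, adjusted p = 0.000147). The male-biased gene Hsd3b5 rose from 13.7 ± 19.2 to 112 ± 40.7 FPKM (log2 fold change 3.69, adjusted p = 0.000229). In GRCm38 Manf lies at chromosome 9, 106838312 to 106891979, Sqle at chromosome 15, 59315077 to 59331192 and Fads2 at chromosome 19, 10062765 to 10101746.

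By limma, 2533 of 9575 genes tested changed, 1364 higher and 1169 lower after dosing. The counts were 1182 and 1246 as TPM, 1337 and 1307 with median-ratio scaling and 1439 and 1290 with quantile scaling. Without model 1_4 and BBBPH 2_2 the count was 1917, and without control 2_1 as well 1822. Among the largest rises by the rule were Hsd3b5, Slco1a1, Igfbp2, the glucose-6-phosphatase G6pc and the leptin receptor Lepr, with log2 fold changes of 2.47 for Slco1a1, 2.16 for Igfbp2, 2.10 for G6pc and 1.97 for Lepr. The largest falls were in Cfd, the heat-shock gene Hspa1b, the methyltransferase Bhmt, Scd1, the lipid droplet gene Cidea and the pseudogene Mup-ps16, with -4.11 for Cfd, -3.35 for Hspa1b, -2.95 for Bhmt, -2.79 for Cidea and -2.58 for Mup-ps16. The call of Cidea ended with voom (adjusted p = 0.0958).

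**Figure D3:**
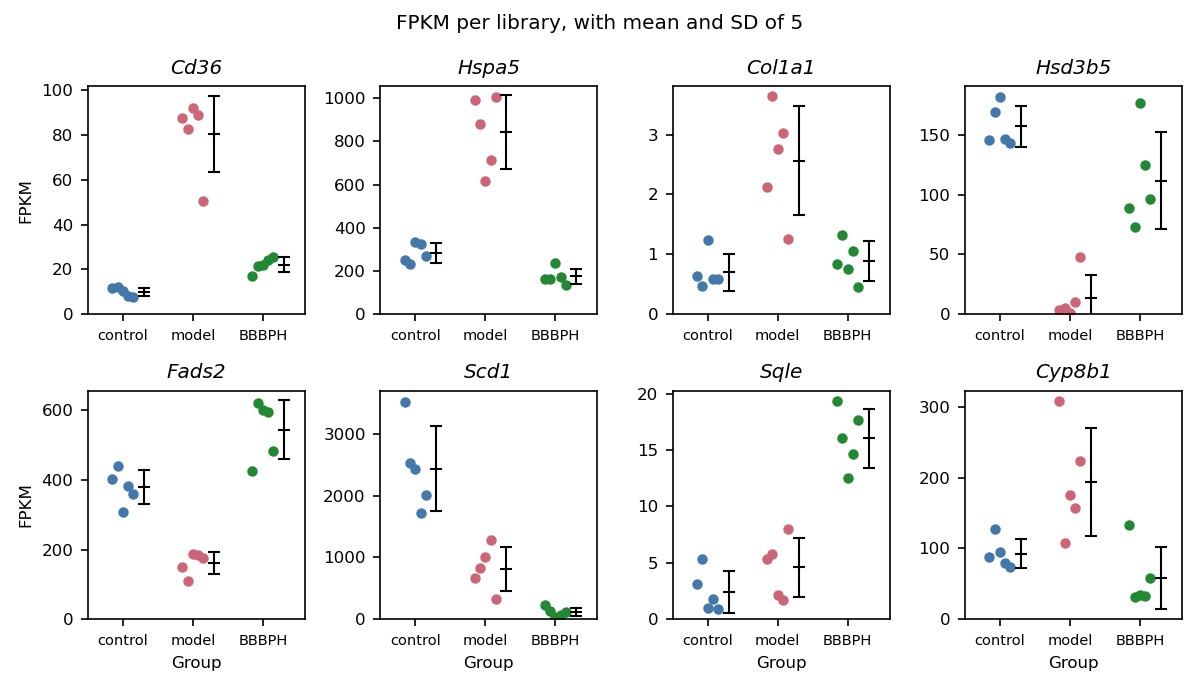
FPKM of 8 genes in each of the 15 libraries (points, 5 per group), with the mean and SD of each group beside them on linear axes that start at 0. Cd36 and Hspa5 are highest in the model, and Scd1 falls from control to model to BBBPH.

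Of unfolded protein response genes, 1 of 22 rose and 18 fell (20 changed adjusted over the list alone). Together they fell (relative median -1.17, adjusted p = 1.12e-15), with adjusted p = 0.431 with an estimated correlation. Of antioxidant and NRF2 target genes, 2 of 20 rose and 11 fell (16 changed adjusted over the list alone), with log2 fold changes of -1.13 for Srxn1 and 1.42 for Gstp1. The members fell as a list (relative median -0.39, adjusted p = 0.000267), with adjusted p = 0.431 with an estimated correlation. Of cholesterol synthesis genes, 18 of 24 rose and 0 fell (21 changed adjusted over the list alone), and the list rose (relative median 0.74, adjusted p = 1.29e-08), with adjusted p = 0.439 with an estimated correlation. Of lipogenesis genes, 12 of 19 rose and 1 fell (15 changed adjusted over the list alone). This list rose (relative median 1.23, adjusted p = 4.08e-06), with adjusted p = 0.439 with an estimated correlation. Scd1 was the single member that fell, and log2 fold changes of others were 1.56 for Fads1, 1.86 for Fasn and 1.25 for Srebf1. Of lipid droplet genes, 4 of 20 rose and 7 fell (11 changed adjusted over the list alone), with a log2 fold change of -1.93 for Plin4. They did not pass as a list (relative median -0.09, adjusted p = 0.0796) except without model 3_4 or BBBPH 2_1 or with no filter or 20 top genes out (adjusted p = 0.0216 to 0.0454). Plin2 had 298 ± 117 FPKM after dosing and was not called (log2 fold change 0.04, adjusted p = 0.928). Of fatty acid oxidation genes, 8 of 30 rose and 3 fell (13 changed adjusted over the list alone), with log2 fold changes of 0.54 for Cpt1a and 0.43 for Eci2, the former a carnitine palmitoyltransferase. Together they did not pass (relative median 0.15, adjusted p = 0.131) except without BBBPH 3_2 (adjusted p = 0.0449). Apolipoprotein genes (relative median 0.02, adjusted p = 0.461) and glucose metabolism genes (relative median 0.11, adjusted p = 0.381) did not pass as lists. Log2 fold changes were 1.14 for Apom, 0.83 for Apoa1, 1.40 for Gys2 and 1.12 for Tkfc.

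**Figure D4:**
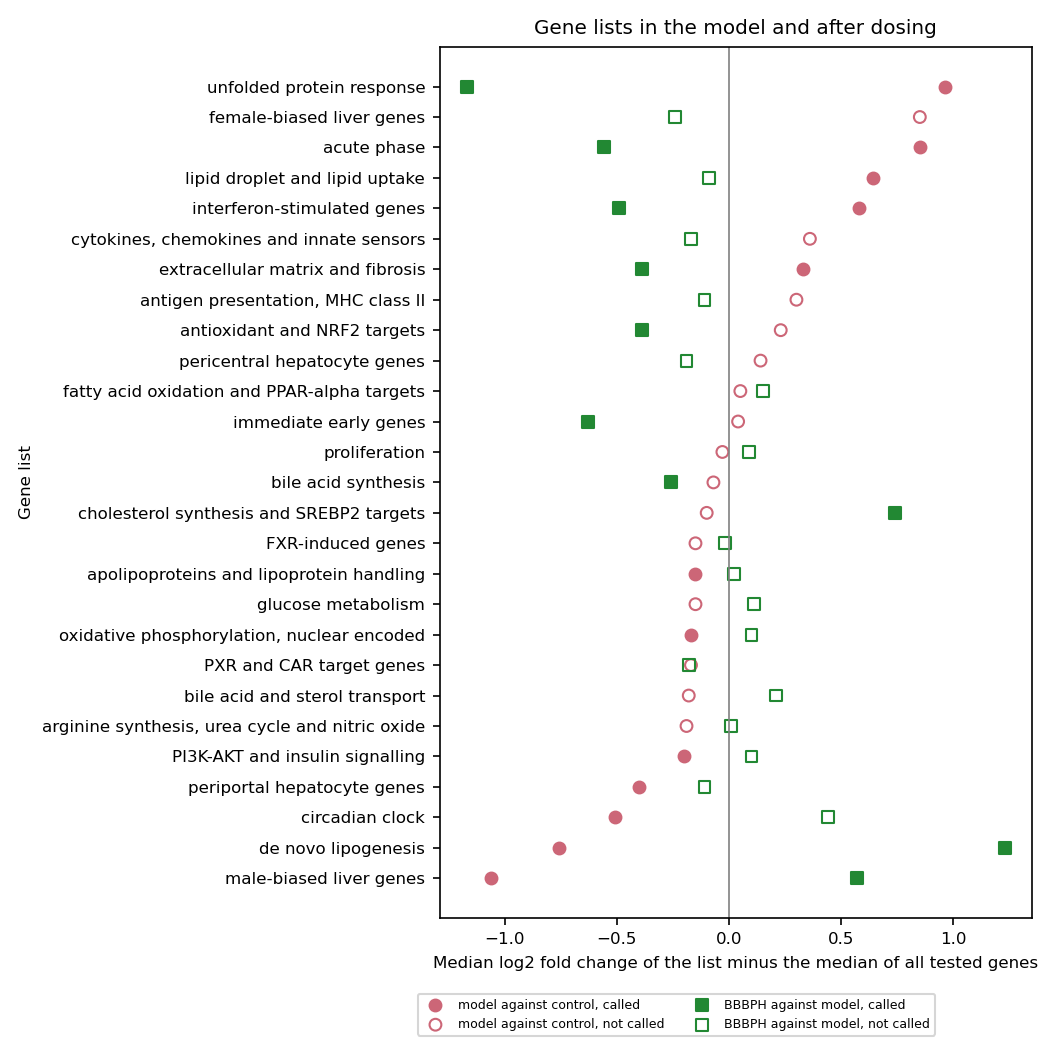
Median log2 fold change of each of 27 gene lists minus the median of all tested genes, for model against control (circles) and BBBPH against model (squares); filled symbols passed the test with the preset correlation. Unfolded protein response genes lie at 0.96 in the model comparison and at -1.17 after dosing.

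Of bile acid synthesis genes, 1 of 17 rose and 6 fell (10 changed adjusted over the list alone). As a list they fell (relative median -0.26, adjusted p = 0.0379), with adjusted p = 0.708 with an estimated correlation, and the first call ended without model 1_1, 2_1, BBBPH 2_2, 3_1 or 3_2 or with median-ratio scaling (adjusted p = 0.0529 to 0.0609). Cyp8b1 fell from 194 ± 76.0 to 57.8 ± 43.8 FPKM (log2 fold change -1.89, adjusted p = 0.00119) and Hsd3b7 from 188 ± 20.9 to 112 ± 24.3 FPKM (log2 fold change -0.76, adjusted p = 0.000607), while the oxysterol hydroxylase gene Cyp39a1 rose from 8.53 ± 2.64 to 31.1 ± 9.26 FPKM (log2 fold change 1.75, adjusted p = 5.70e-05). Cyp7a1 had 12.3 ± 14.5 FPKM after dosing and was not called (log2 fold change -1.88, adjusted p = 0.0506) except without model 3_4, BBBPH 2_2 or 3_4 or with a filter at 5 FPKM, TPM, median-ratio scaling, quantile scaling, voom or a clock covariate (adjusted p = 0.00761 to 0.049). Nr1h4 rose from 53.1 ± 7.74 to 81.6 ± 9.90 FPKM (log2 fold change 0.61, adjusted p = 0.00089) and Nr1i2 from 24.6 ± 1.20 to 34.9 ± 3.94 FPKM (log2 fold change 0.48, adjusted p = 0.000824). Nr0b2, with 18.1 ± 7.49 FPKM (log2 fold change 0.41, adjusted p = 0.411), Cyp3a11, with 527 ± 82.0 (log2 fold change -0.02, adjusted p = 0.964), and Cyp2b9, with 42.4 ± 28.4 (log2 fold change -0.99, adjusted p = 0.173), were not called. The change of Nr0b2 was 0.03 without model 1_4 and 0.21 without BBBPH 3_1. FXR-induced genes did not pass as a list (relative median -0.02, adjusted p = 0.868), with mean and median of opposite sign. Among them Abcb11 fell from 77.6 ± 4.93 to 42.7 ± 8.52 FPKM (log2 fold change -0.86, adjusted p = 0.000222), and the hormone gene Fgf21 rose from 8.59 ± 4.25 to 33.2 ± 32.2 FPKM (log2 fold change 1.57, adjusted p = 0.0291), a call that ended without model 1_4, 2_3, BBBPH 2_1 or 3_1 or with no filter, a robust fit, 2 libraries out or 3 libraries out (adjusted p = 0.0502 to 0.0715). Transporters (relative median 0.21, adjusted p = 0.405) did not pass either, nor did PXR and CAR targets (relative median -0.18, adjusted p = 0.0796), the latter except without model 1_4 or 2_3 or with no filter, 2 libraries out, 3 libraries out or 20 top genes out (adjusted p = 0.0151 to 0.0433). The named members had log2 fold changes of 1.13 for Abcg5, -0.81 for Abcc3, 1.23 for Por and -1.23 for Aldh1a1.

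Of matrix genes, 0 of 18 rose and 12 fell (12 changed adjusted over the list alone), and the list fell (relative median -0.39, adjusted p = 5.36e-06), with adjusted p = 0.439 with an estimated correlation. Col3a1 fell from 9.23 ± 2.11 to 3.93 ± 1.03 FPKM (log2 fold change -1.05, adjusted p = 0.000215). Stellate cell and fibroblast markers moved beside them: 1 of 14 rose and 4 fell (6 changed adjusted over the list alone), with log2 fold changes of -0.65 for Col14a1 and -0.31 for Hgf. The list fell (relative median -0.17, adjusted p = 0.0389), with adjusted p = 0.668 with an estimated correlation, and the first call ended without model 1_4, 2_1, BBBPH 2_2 or 3_4 or with median-ratio scaling, 2 libraries out or 3 libraries out (adjusted p = 0.0521 to 0.107). Of interferon-stimulated genes, 1 of 20 rose and 13 fell (16 changed adjusted over the list alone), with log2 fold changes of -1.31 for Rsad2 and -0.87 for Ifit3. They fell as a list (relative median -0.49, adjusted p = 2.05e-06), with adjusted p = 0.584 with an estimated correlation. Of cytokine, chemokine and innate sensor genes, 2 of 22 rose and 8 fell (10 changed adjusted over the list alone). The list did not pass (relative median -0.17, adjusted p = 0.0636) except without model 1_1, 2_3, 3_4, BBBPH 3_1 or 3_4 or with no filter or 20 top genes out (adjusted p = 8.02e-05 to 0.047). Ccl2 fell from 5.02 ± 2.46 to 1.09 ± 0.445 FPKM (log2 fold change -1.44, adjusted p = 0.000703), and Cxcl10 had a log2 fold change of -1.43. Of acute-phase genes, 0 of 20 rose and 3 fell (1 changed adjusted over the list alone). Together they fell (relative median -0.56, adjusted p = 0.00164), with adjusted p = 0.764 with an estimated correlation, and the first call ended without model 1_4 or with 2 libraries out or 3 libraries out (adjusted p = 0.054 to 0.0791). The relative median of the list was -0.22 without model 1_4. Log2 fold changes were -1.73 for Orm3 and -3.52 for Saa2, the latter -2.12 without model 1_4, and the call of Saa2 ended without BBBPH 2_2, 3_1 or 3_2 or with no filter, a robust fit, a 2-group fit or a clock covariate (adjusted p = 0.0547 to 0.0691). Of immediate early genes, 0 of 14 rose and 7 fell (7 changed adjusted over the list alone), with log2 fold changes of -1.09 for Btg2 and -1.56 for Atf3. The members fell as a list (relative median -0.63, adjusted p = 0.00101), with adjusted p = 0.668 with an estimated correlation. Of male-biased genes, 7 of 22 rose and 2 fell (12 changed adjusted over the list alone). The list rose (relative median 0.57, adjusted p = 0.0169), with adjusted p = 0.764 with an estimated correlation, and the first call ended without model 2_1, BBBPH 2_1 or 3_1 (adjusted p = 0.0515 to 0.104).

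Of clock genes, 8 of 15 rose and 4 fell (13 changed adjusted over the list alone), with a log2 fold change of 0.67 for Cry2, and the list did not pass (relative median 0.44, adjusted p = 0.0796) except without BBBPH 2_1 (adjusted p = 0.0419). Of arginine, urea cycle and nitric oxide genes, 2 of 19 rose and 7 fell (11 changed adjusted over the list alone), with log2 fold changes of -1.30 for Oat and -0.50 for Glud1. They did not pass as a list (relative median 0.01, adjusted p = 0.352), with mean and median of opposite sign. Nos3 fell from 1.48 ± 0.225 to 0.886 ± 0.227 FPKM (log2 fold change -0.40, adjusted p = 0.00549). Ass1, with 1026 ± 292 FPKM (log2 fold change 0.08, adjusted p = 0.806), and Arg1, with 832 ± 128 (log2 fold change 0.24, adjusted p = 0.181), were not called, the latter except without BBBPH 3_1 (adjusted p = 0.037). Lists of insulin signalling (relative median 0.10, adjusted p = 0.138), MHC class II (relative median -0.11, adjusted p = 0.507), female-biased (relative median -0.24, adjusted p = 0.886), periportal (relative median -0.11, adjusted p = 0.352) and proliferation genes (relative median 0.09, adjusted p = 0.564) did not pass, the last with signs that differed. For female-biased genes the relative median was -0.01 without BBBPH 2_1 and -0.13 without model 1_1 or without model 2_1. Oxidative phosphorylation genes (relative median 0.10, adjusted p = 0.0796) passed without model 1_1, 3_4 or BBBPH 3_1 or with no filter (adjusted p = 0.0139 to 0.0492). Pericentral genes (relative median -0.19, adjusted p = 0.138) did so without model 1_4 or with no filter (adjusted p = 0.0314 and 0.028). In these lists log2 fold changes were 1.66 for Egfr, 0.41 for Pik3cb, -1.89 for Cyp2a22, 1.76 for Acot3, -0.92 for Etnppl, -1.34 for Gldc, 1.18 for Tk1, 0.98 for Rrm2, 0.32 for Cyc1, 0.29 for Cox7a2 and -1.33 for Rhbg. The call of Cox7a2 ended without model 1_1, 1_4, 2_3, BBBPH 2_2 or 3_2 or with 2 libraries out, 3 libraries out or a clock covariate (adjusted p = 0.0539 to 0.147) and that of Cyc1 with 2 libraries out or 3 libraries out (adjusted p = 0.0758 and 0.0906). Markers of hepatocytes (relative median 0.04, adjusted p = 0.461), Kupffer cells (relative median 0.04, adjusted p = 0.366), neutrophils (relative median -0.63, adjusted p = 0.381), endothelium (relative median 0.07, adjusted p = 0.614), erythroid cells (relative median 0.63, adjusted p = 0.381) and muscle (relative median 0.00, adjusted p = 0.943) did not pass as lists, except neutrophils with 3 libraries out (adjusted p = 0.0392). For neutrophils the relative median was -0.27 without model 1_4 and -0.37 without BBBPH 2_1. Macrophage markers (relative median -0.38, adjusted p = 0.0636) passed without model 1_1, 3_4 or BBBPH 2_2 or with no filter or 20 top genes out (adjusted p = 0.000783 to 0.0323). Pancreas and gut markers (relative median 1.59, adjusted p = 0.0636) did so without model 3_4, BBBPH 3_1, 3_2 or 3_4 or with no filter or TPM (adjusted p = 0.0234 to 0.0491), but rested on BBBPH 2_2, without which the relative median was -0.05. Single markers had log2 fold changes of 0.48 for Ahsg, -1.52 for Mmp12, -0.73 for Trem2, 1.08 for Marco, 0.52 for Timd4, -0.60 for Alas2, 0.81 for Hbb-bt and 0.67 for Lipe. The call of Marco ended without model 1_1 or BBBPH 3_2 or with a clock covariate (adjusted p = 0.0526 to 0.0612), that of Timd4 without model 1_1, 1_4, 2_1, 2_3, BBBPH 2_2, 3_1, 3_2 or 3_4 or with no filter, a 2-group fit, 2 libraries out, 3 libraries out or a clock covariate (adjusted p = 0.0504 to 0.11) and that of Hbb-bt without model 1_1, 1_4, 2_1, BBBPH 2_2 or 3_1 or with no filter, 2 libraries out or 3 libraries out (adjusted p = 0.0534 to 0.133). None of 14 marker scores was called by exact permutation tests, and 3 had an unadjusted p under 0.05: stellate cells (BBBPH minus model -0.54, p = 0.0397), adipocytes (-0.48, p = 0.0238) and pancreas and gut (0.78, p = 0.0159). Without BBBPH 2_2 the last was 0.21, and without model 2_3 that of adipocytes was -0.31. Ribosomal protein genes took 5.45 ± 0.19% of the FPKM after dosing (exact permutation p = 0.00794 against the model and 0.103 against control). Among genes named as changed, the libraries of both groups overlapped for Col1a1, Cyp8b1, Fgf21, Saa2, Atf3, Pik3cb, Gldc, Cyc1, Mmp12, Trem2, Marco, Timd4 and Hbb-bt, and for no others.

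The next comparison asked how far dosing moved genes against the direction of the model. Of the 3692 genes that changed in the model, 1442 (39.1%) changed with the opposite sign after dosing. Of these, 919 rose and then fell and 523 fell and then rose, where lists drawn independently would share 349.8 and 117.8. In both comparisons 41 rose and 6 fell, where 408.1 and 101 would be shared. The 6 genes named by the rule were Cd36, Plin4, Sel1l, Syvn1, the UDP-glycosyltransferase gene Ugt3a1 and Ugdh, whose enzyme makes UDP-glucuronate. Ugt3a1 went from 23.1 ± 1.0 to 54.9 ± 6.29 and then 26.4 ± 3.21 FPKM, and Ugdh from 39.6 ± 4.96 to 100.1 ± 15.9 and then 35.0 ± 4.46. Both comparisons used the same 5 model libraries, which gives opposite fold changes with no effect at all. Over genes, which are not independent replicates, r was -0.6728, against a mean of -0.4998 (-0.8464 to -0.0344) in 100 simulations of unchanged groups. The covariance was -0.0993, against -0.0123 (-0.0271 to -0.000704) in the simulations. With the model libraries split into separate sets for both comparisons, in 20 ways, r averaged -0.5698 and the share of opposite calls 30.2% (18.8 to 44.1). Without model 1_4 and BBBPH 2_2, 1137 genes had opposite calls.

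**Figure D5:**
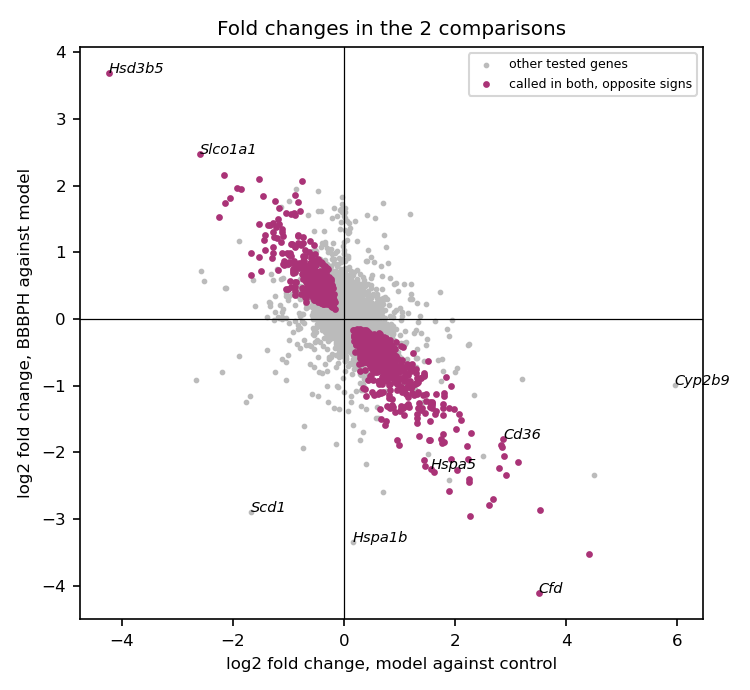
Log2 fold change in BBBPH against model plotted over that in model against control for the 9575 tested genes, each point a gene. The 1442 genes called in both with opposite signs are coloured. The shared model libraries alone tilt such a plot, with r at -0.4998 in simulations of unchanged groups.

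The comparison of BBBPH with control libraries asked how far the dosed mice remained from the control mice. Scd1 was lower, from 2442 ± 689 to 115 ± 70.6 FPKM (log2 fold change -4.57, adjusted p = 1.77e-05), and Sqle higher, from 2.43 ± 1.85 to 16.1 ± 2.65 FPKM (log2 fold change 2.45, adjusted p = 0.000369). Cyp2b9 (log2 fold change 4.96 ± 0.52 SE, adjusted p = 4.88e-05) and Cd36 (log2 fold change 1.07 ± 0.16 SE, adjusted p = 0.000571) were above control, and so was Fgf21 (log2 fold change 2.76 ± 0.50 SE, adjusted p = 0.00148). Gadd45g, a growth arrest gene, was lower, from 67.4 ± 42.4 to 4.94 ± 3.49 FPKM (log2 fold change -3.59, adjusted p = 0.000797), and so was Hspa1b, from 56.1 ± 19.6 to 5.04 ± 1.34 FPKM (log2 fold change -3.19, adjusted p = 0.000114). By limma 2691 genes changed, 2337 higher and 354 lower, against 2184 and 356 as TPM, 667 and 944 with median-ratio scaling and 691 and 849 with quantile scaling. Median-ratio scaling shared 1021 of the calls. The count was 2318 without model 1_4 and BBBPH 2_2, and 2110 without control 2_1 as well. Of the 3692 genes that changed in the model, 1420 were called here with the same sign, 85 with the opposite sign and 2187 not, which does not show that those equal control. Both comparisons with control used the same 5 control libraries, which favours the same sign with no effect at all. No overlap expected from this sharing was computed, so the 1420 genes do not show how many changes of the model persisted.

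Of periportal genes, 1 of 20 rose and 9 fell (11 changed adjusted over the list alone), with log2 fold changes of -1.97 for Etnppl and -0.79 for Cyp2f2. As a list they fell (relative median -0.43, adjusted p = 2.97e-09), with adjusted p = 0.0299 with an estimated correlation, the single list call of the 3 comparisons to pass with it. Of cholesterol synthesis genes, 17 of 24 rose and 0 fell (20 changed adjusted over the list alone), with log2 fold changes of 1.40 for Hmgcs1 and 0.73 for Srebf2. They rose as a list (relative median 0.67, adjusted p = 3.65e-06), with adjusted p = 0.46 with an estimated correlation. Of fatty acid oxidation genes, 16 of 30 rose and 0 fell (18 changed adjusted over the list alone), with log2 fold changes of 1.92 for Vnn1 and 0.47 for Acadl. Together they rose (relative median 0.19, adjusted p = 0.00385), with adjusted p = 0.621 with an estimated correlation, and the first call ended without control 2_1 or BBBPH 2_1 (adjusted p = 0.0546 and 0.0572). Of lipid droplet genes, 10 of 20 rose and 0 fell (11 changed adjusted over the list alone), with log2 fold changes of 1.17 for Plin3 and 0.86 for Plin2. The members rose as a list (relative median 0.36, adjusted p = 0.0284), with adjusted p = 0.511 with an estimated correlation, and the first call ended without control 2_2 or BBBPH 2_1 (adjusted p = 0.0619 and 0.073), and that of Plin2 ended with median-ratio scaling (adjusted p = 0.0682). Of bile acid synthesis genes, 4 of 17 rose and 5 fell (13 changed adjusted over the list alone), with log2 fold changes of -0.55 for Slc27a5 and -1.13 for Cyp2c70, a bile acid ligase and an enzyme of muricholic acid synthesis. The list fell (relative median -0.29, adjusted p = 0.000598), with adjusted p = 0.407 with an estimated correlation. Cyp7a1 was lower (log2 fold change -2.03 ± 0.67 SE, adjusted p = 0.0357), a call that ended without control 1_1, 1_5, 2_1, 2_2, BBBPH 2_1, 3_1 or 3_2 or with no filter, a robust fit, a 2-group fit or 3 libraries out (adjusted p = 0.0556 to 0.0841). Cyp8b1 was not called (log2 fold change -0.89, adjusted p = 0.0697) except without BBBPH 2_1 or with library weights or a clock covariate (adjusted p = 0.00423 to 0.0499). Nr1h4 (log2 fold change 0.71 ± 0.11 SE, adjusted p = 0.00062) and Nr0b2 (log2 fold change 1.39 ± 0.35 SE, adjusted p = 0.0097) were higher, and Nr1i2 was not called (log2 fold change 0.19, adjusted p = 0.101) except without control 1_1 (adjusted p = 0.0339). Of PXR and CAR targets, 2 of 21 rose and 5 fell (9 changed adjusted over the list alone), among them Ces2a (log2 fold change -1.14 ± 0.13 SE, adjusted p = 9.06e-05). They fell as a list (relative median -0.22, adjusted p = 0.000187), with adjusted p = 0.407 with an estimated correlation, and the first call ended with median-ratio scaling (adjusted p = 0.0513). Cyp3a11 was not called (log2 fold change -0.78, adjusted p = 0.0591) except with median-ratio scaling, library weights, a 2-group fit, 2 libraries out or 3 libraries out (adjusted p = 0.00768 to 0.0401).

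Of unfolded protein response genes, 2 of 22 rose and 4 fell (6 changed adjusted over the list alone), with log2 fold changes of -0.86 for Dnajb9 and -0.85 for Herpud1. Together they fell (relative median -0.22, adjusted p = 0.000187), with adjusted p = 0.511 with an estimated correlation, and the relative median was -0.13 without BBBPH 2_1 and -0.14 without control 2_1 or without BBBPH 3_4. Of immediate early genes, 0 of 14 rose and 4 fell (4 changed adjusted over the list alone), with log2 fold changes of -2.99 for Myc and -0.51 for Klf2. The members fell as a list (relative median -0.55, adjusted p = 1.07e-07), with adjusted p = 0.407 with an estimated correlation, and the relative median was -0.36 without control 3_4. Of male-biased genes, 0 of 22 rose and 2 fell (2 changed adjusted over the list alone), with log2 fold changes of -1.22 for Ugt2b38 and -1.86 for Cyp4a12b. As a list they fell (relative median -0.48, adjusted p = 9.59e-07), with adjusted p = 0.407 with an estimated correlation, and the relative median was -0.31 without BBBPH 2_2. Of arginine, urea cycle and nitric oxide genes, 1 of 19 rose and 6 fell (10 changed adjusted over the list alone), with log2 fold changes of -0.73 for Cps1, -0.68 for Gls2 and -0.72 for Ass1. The list fell (relative median -0.15, adjusted p = 0.000144), with adjusted p = 0.511 with an estimated correlation, and the call of Ass1 ended without control 1_1 or with quantile scaling (adjusted p = 0.0548 and 0.0586). Arg1 (log2 fold change -0.05, adjusted p = 0.781), Nos3 (log2 fold change -0.02, adjusted p = 0.912), Srebf1 (log2 fold change 0.43, adjusted p = 0.201), Col1a1 (log2 fold change 0.15, adjusted p = 0.544) and Ccl2 (log2 fold change 0.34, adjusted p = 0.324) were not called. The change of Srebf1 was 0.26 without control 3_4. Of insulin signalling genes, 4 of 23 rose and 1 fell (5 changed adjusted over the list alone), with log2 fold changes of -0.59 for Foxo3 and 0.32 for Pik3r2. They fell as a list (relative median -0.15, adjusted p = 0.042), with adjusted p = 0.621 with an estimated correlation, and the first call ended without control 3_4, BBBPH 2_1 or 3_4 or with no filter (adjusted p = 0.067 to 0.19), and that of Pik3r2 ended with median-ratio scaling or quantile scaling (adjusted p = 0.123 and 0.0956). Of hepatocyte markers, 1 of 14 rose and 1 fell (2 changed adjusted over the list alone), with log2 fold changes of -1.62 for Tat and 0.43 for Apoa1. Together they fell (relative median -0.24, adjusted p = 0.00385), with adjusted p = 0.407 with an estimated correlation, and the call of Apoa1 ended without control 2_1, 2_2, 3_4, BBBPH 2_1, 2_2, 3_2 or 3_4 or with no filter, median-ratio scaling or quantile scaling (adjusted p = 0.0504 to 0.456). Muscle markers passed as lower (relative median -1.26, adjusted p = 0.00267), with adjusted p = 0.511 with an estimated correlation, and the first call ended without control 2_1 or with median-ratio scaling or 3 libraries out (adjusted p = 0.158 to 0.226). The relative median was -0.13 without control 2_1. Mylpf (log2 fold change -1.09, adjusted p = 0.223) and Tnnt3 (log2 fold change -1.28, adjusted p = 0.283) were not called. Their changes were -0.20 and -0.07 without that library. The other 23 lists did not pass, with adjusted p from 0.0818 to 0.975. Signs of median, mean and test differed for transporters, FXR-induced, acute-phase, glucose, pericentral and erythroid genes. Among these, a list passed for FXR-induced genes without control 2_2 (adjusted p = 0.0459), apolipoproteins without BBBPH 3_4 (adjusted p = 0.042), interferon-stimulated genes without control 1_1, 3_4, BBBPH 3_1 or 3_4 (adjusted p = 0.00769 to 0.0446), antioxidant and NRF2 targets with 3 libraries out (adjusted p = 0.0457), oxidative phosphorylation genes without control 3_4 or with median-ratio scaling (adjusted p = 0.00674 and 0.017), female-biased genes without control 1_5 or with a pseudocount of 0.1 or median-ratio scaling (adjusted p = 0.0067 to 0.0448), stellate cell markers with no filter (adjusted p = 0.0341) and pancreas and gut markers with median-ratio scaling (adjusted p = 0.0267). In these lists log2 fold changes were 0.98 for Fasn, 0.67 for Fads1, -0.45 for Cyp4f15, -0.40 for Abcb11, 0.63 for Abcc3, 0.49 for Slco2b1, 1.54 for Apoa4, -0.54 for Apoc1, 0.78 for Lbp, 1.64 for Saa3, 0.67 for Ccl6 and 0.97 for Il1rn. Further ones were 0.40 for Sparc, 0.52 for Col4a1, -1.69 for Pfkfb3, -1.30 for Pck1, -0.87 for Per1, 0.50 for Hlf, 1.41 for Tbx3, 0.35 for Cygb, 0.42 for Ngfr, -1.95 for Fabp5 and 0.72 for Cd63. The call ended for Abcb11 without control 1_1, 2_1, 3_4, BBBPH 2_1, 2_2, 3_1 or 3_4 or with no filter, a 2-group fit, 2 libraries out or 3 libraries out (adjusted p = 0.0567 to 0.139) and for Ngfr without control 1_5, 2_2 or BBBPH 3_2 or with median-ratio scaling or quantile scaling (adjusted p = 0.0567 to 0.219). It also ended for Sparc, Col4a1 and Cygb with median-ratio or quantile scaling (adjusted p = 0.0745 to 0.149).

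None of the 14 marker scores was called here by exact permutation tests, and 4 had an unadjusted p under 0.05. Stellate (BBBPH minus control 0.92) and endothelial (0.80) scores had adjusted p = 0.0556 and passed without BBBPH 2_1 or 3_1 (adjusted p = 0.037). The macrophage score (0.55, exact p = 0.0159) passed without BBBPH 2_1 (adjusted p = 0.037), and that of pancreas and gut (0.76, exact p = 0.0238) without BBBPH 3_1 (adjusted p = 0.037). The difference in pancreas and gut rested on BBBPH 2_2, without which it was 0.05. Among genes named as changed, BBBPH and control libraries overlapped for Plin2, Cyp7a1, Dnajb9, Ass1, Pik3r2, Fasn, Abcb11, Slco2b1, Ccl6, Ngfr, Fabp5 and Cd63, and for no others. The files give no strand setting, and fragments of some named genes could not be told from those of an overlapping neighbour. These pairs were Abcg5 and Abcg8, Plin4 and Hdgfl2, Col4a1 and Col4a2, Cxcl10 and Art3, Tk1 and Afmid, Gls2 and Spryd4, Oat and Fgfr2, Tkfc with Cyb561a3 and Ddb1, Manf with Dcaf1 and Rbm15b, and Syvn1 and Mrpl49. Fragments of close paralogs, such as Saa1 and Saa2, Hspa1a and Hspa1b, the globins and the Cyp2b, Cyp3a, Cyp4a and Mup families, were not separated here.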

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

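Tests of depth, of the pancreas genes and of the clock correlation were chosen only after the result was seen. In 489 groups of 5 libraries (149 named genes and 14 marker scores), 37 held a library far from the other 4 by Dixon's ratio, and chance alone gives about 1 in 20 groups.

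More genes rose than fell in model against control (2865 against 827 on the deposited scale). A difference in library depth is argued against by group means of fragments counted that differed by at most 4.3%. With the 20 most abundant genes left out and the rest rescaled, 67.3% of calls were still higher, between the bounds set for and against them. A single scale factor per library cannot be told apart from a broad change: median log2 changes of 5 equal groups of genes by level ranged over 0.13, between the bounds of 0.05 and 0.15. An earlier test, 45% higher after median-ratio scaling, was set aside because such factors centre the genes by construction.

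BBBPH 2_2 had a pancreas and gut score of 2.51 (others -0.22 to 0.21). All 10 pancreas genes tested exceeded 10 times the highest of the other 14 libraries, and where their transcripts came from stays open. Cela1 alone was above 2 FPKM elsewhere, at up to 26.32, and Ctrb1, Prss2 and Pnlip had 978, 581.1 and 561 FPKM. An effect of dosing is argued against by 0 of 10 genes whose median in the other 4 BBBPH libraries exceeded all control and model libraries. Another tissue under this label is argued against by albumin, at 110.2% of its share in those libraries. Its neutrophil score was 1.66 (others -0.64 to -0.12), for which no explanation was tested.

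Clock genes varied between libraries of 1 group: Dbp had 3.51 FPKM in BBBPH 2_1 and 52.1 in BBBPH 3_2. Scores of morning-peak and evening-peak clock genes, less group means, correlated over 15 libraries with r = -0.93 (permutation p = 5.0e-05; rho = -0.89, permutation p = 0.00011; r = -0.83 without the 2 farthest, 2 pairs of scores computed). Without genes whose values had been seen before, 8 genes gave r = -0.95, so collection at different times of day may contribute. Clock state as the cause of the calls in BBBPH against model is argued against by 84.2% still called with the score as covariate. Group differences of the score had exact permutation p of 0.222, 0.294 and 0.738, and no biological explanation was tested.

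The remaining outlying values are given by library, with the other 4 libraries of the group in parentheses. In model 1_4, FPKM was 14965 for Saa2 (61.6 to 194), 853 for Mt2 (32.6 to 83.2), 16.5 for Myc (1.36 to 3.07), 43.3 for Gadd45g (3.65 to 7.35) and 131 for Acadl (170 to 171). In model 3_4 it was 50.6 for Cd36 (82.6 to 92.2), 226 for Apom (159 to 171) and 33.5 for Hbb-bt (22 to 24.7), and model 2_3 had an adipocyte score of 1.18 (-0.04 to 0.27). Control 2_1 had 46.7 FPKM of Mylpf (0.804 to 1.82), 70 of Tnnt3 (0 to 0.145), 8.17 of Srxn1 (6.31 to 6.56), 1.24 of Col1a1 (0.464 to 0.635) and 1.04 of Cidea (0 to 0.0952). Its scores were 3.60 for skeletal muscle (-0.25 to -0.21), 1.25 for adipocytes (-0.63 to -0.34), 0.51 for neutrophils (-0.72 to -0.63) and -0.24 for dendritic cells (-0.65 to -0.54). Control 1_5 had 20.6 FPKM of Sel1l (25 to 26.7) and 0.862 of Cyp2a22 (0.181 to 0.296), and control 2_2 had 371 of Glud1 (295 to 306). Control 3_4 had 2.58 of Cdkn1a (0.936 to 1.21), 121 of Gls2 (147 to 157), 630 of Arg1 (892 to 960) and 1.28 of Rrm2 (2.25 to 2.57). BBBPH 2_1 had 10 of Cdkn1a (0.376 to 0.73), 742 of Car3 (1008 to 1057), 64.4 of Nr1h4 (83.1 to 88.4) and 31.1 of Fabp5 (12.9 to 13.4). BBBPH 3_1 had 31.3 of Nr0b2 (12.6 to 16.2) and 520 of Ass1 (1051 to 1246), and BBBPH 3_2 had 57.7 of Abcb11 (36.5 to 41.2) and 12.1 of Saa3 (21.7 to 27.4). BBBPH 3_4 had 389 of Cyp3a11 (525 to 591) and 2.55 of Btg2 (1.86 to 2.02).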

How the results depend on the processing

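Tests with voom, without the 20 most abundant genes, without the libraries that stood apart and with a clock covariate were chosen only after the result was seen. Counts of genes changed stayed within 1.5 times their value under every alternative except those named here, where the cause was not tested unless stated. With a filter at 5 FPKM, which tests 5578 genes, 2259, 1634 and 1502 genes changed in model against control, BBBPH against model and BBBPH against control. With a fold minimum, which removes calls by construction, 255, 223 and 118 changed, and 116 had opposite calls. BBBPH against control gave 1611 genes with median-ratio scaling and 1540 with quantile scaling. Median-ratio scaling kept 62.6% of the calls in model against control, 97.1% in BBBPH against model and 37.9% in BBBPH against control, and 41.4% of calls in the last were higher. With the full number as a replicate block, which leaves 4 residual degrees of freedom, 1315, 305 and 185 genes changed, 216 had opposite calls, and the acute phase list turned its direction in BBBPH against model (adjusted p = 0.312) and in BBBPH against control (adjusted p = 0.00591). With the first digit as a replicate block, 3586, 1795 and 1844 genes changed. Without 1 library, 3112 to 3546, 2084 to 2414 and 1887 (without BBBPH 3_2) to 2803 genes changed, with 1210 to 1449 opposite calls. Lists called numbered 13 to 18 (15 with all), 8 to 16 (11) and 10 to 14 (13), with 8 reached without model 2_1, and marker scores called 0 to 5 (4), 0 to 0 (0) and 0 to 3 (0). With no filter 19 lists were called in BBBPH against model. With an estimated correlation 0, 0 and 1 lists were called. Without the 3 libraries that stood apart, 0 marker scores were called in model against control, which fewer arrangements alone can give. Of 108 values of lists, 9 lost and 6 gained a call with the full-number block, 1 of each with its direction turned, and 2 and 4 with the first-digit block. Of 228 values of named genes, 94 lost their call with the full-number block, 88 with the fold minimum, 11 each with median-ratio scaling, quantile scaling and the first-digit block, 9 with no filter, 5 with robust=TRUE and 2 with voom. Other splits of the 10 libraries of a comparison (100 drawn of 126) called at most 187, 151 and 15 genes, against 3692, 2533 and 2691. The real split was the 1 of 100 as large in each, which argues against a random division of the libraries. Splits cannot address other differences between groups. What depth limits was not tested. A log2 fold change of 0.5 was recovered in simulated data for 68.7% to 77.6% of genes.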

Other observations

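The heat-shock list and the comparison of Scd1 were chosen only after the result was seen. Hspa1b and Hsph1 had by then been seen to fall in BBBPH against model, so they and the paralog Hspa1a were left out of the test given here. Of the 15 genes left, 12 fell and 0 rose in BBBPH against model (median log2 fold change -0.77). Camera gave p = 1.63e-11, and 0.0312 with an estimated correlation. The cochaperone Bag3 went from 36.9 ± 11.7 to 10.4 ± 1.89 FPKM (log2 fold change -1.69, adjusted p = 2.07e-05) and Chordc1 from 29.8 ± 5.06 to 12.6 ± 0.719 (log2 fold change -1.16, adjusted p = 4.76e-06). The mitochondrial chaperones Hspe1 (log2 fold change -0.02, adjusted p = 0.934) and Hspd1 (log2 fold change 0.00, adjusted p = 0.989) were not called. Against control 7 of the 15 were lower in BBBPH libraries and 0 higher (p = 2.14e-11, p = 0.032 with an estimated correlation), and 9 were higher in the model (p = 0.0159, p = 0.4 with an estimated correlation, limma).

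Scd1 moved apart from the other lipogenesis genes. The difference, within each library, between log2 Scd1 and the mean of the 18 other genes of its list describes this. It was 5.81 ± 0.28 in control, 4.67 ± 0.60 in model and 0.73 ± 1.11 in BBBPH libraries, and fell by 3.95 with dosing (exact permutation p = 0.00794, n = 5). The difference restates fold changes already seen, and no cause was tested.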
